A study of Mus musculus with 6 samples.

How the data were processed

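Polyadenylated RNA of C57BL/6 mice homozygous for a knockout of Atxn2, or wild type, was profiled with MACE (massive analysis of cDNA ends), which sequences a fragment near the 3' end of each transcript so that a transcript gives 1 tag whatever its length. The labels give 6 libraries, 1 for each genotype in cerebellum, hippocampus and liver, each a pool of 3 animals at 6 months. The titles carry the same animal numbers in every tissue, so the 3 libraries of a genotype were taken as tissues of the same pool, which the labels do not state outright. The labels' protocol text names midbrain in place of hippocampus and ages in weeks, and the sample labels were followed here.

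The deposited tables hold raw counts of tags per RefSeq record, in sense and antisense orientation, with no normalization, per the file headers. Per the submitters' processing notes the base caller was CASAVA 1.8.2 and the build was mm9, while the deposited tables name a GRCm38 genomic set; the aligner is not given in the sources used here. A tag that matched several records equally well stands in a joint row of up to 3 records, per the file headers. The single-tissue tables also hold the authors' log2 ratio of scaled tags, which equals the ratio of the deposited counts scaled to the library total within 0.0004 wherever both counts are above 0. The counts of the single-tissue tables equal those of the combined table in every row (0 rows differ), so the combined table alone was used, and no separate fit of the single tables was made.

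Sense counts were summed per gene symbol. A joint row went to its named gene when every other record was a predicted gene or pseudogene, and rows of several named genes stayed joint features such as Hba-a1/Hba-a2. This gave 22926 features, 4472 of them joint. Genes whose tags lie mainly in rows shared with near-identical copies, such as Rps27 and Gapdh, are uncertain for that reason. Rows of the mitochondrial genome, of genomic contigs and of tags without a match name no gene and stayed out of library sizes and tests. They took 9.26% to 12.8%, 6.22% to 9.51% and 7.21% to 8.83% of all tags. Antisense tags took 7.75% to 10.5%. Gene tags numbered 1774523 to 2727523 per library, which sets the precision of each ratio. Exact 95% counting intervals (Clopper-Pearson) cover counting error only, since the libraries pool animals. A count of 0 was set to a floor of 3 counts per library when a ratio was formed. Positions are those of RefSeq on GRCm38.p6.

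Across tissues, genotype was tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr by genotype, tissue as block) on 11375 genes, with Benjamini-Hochberg adjustment at 0.05. The 3 libraries of a genotype were taken as tissues of the same pooled animals, so these p-values measure agreement between tissues and not the spread between animals. Gene lists fixed before the data were examined were tested two-sided with camera in limma 3.58.1. The preset correlation was 0.01, and 42 lists had at least 5 tested members. With an estimated correlation, the alternative, camera uses the 2 residual degrees of freedom of the fit, so few lists can pass whatever their correlation. Purkinje cell markers had an estimated correlation of -0.028, below the preset, yet their camera p went from 3.43e-06 to 0.036. Failing this alternative thus does not show that correlation between genes accounts for a list. Within a tissue there is 1 library per genotype and no test was made. Genes were counted by size (an absolute log2 ratio of at least 1, a mean CPM of at least 10, and an interval that excludes equality). List medians were set among 10000 random lists matched on mean expression, with a minimum CPM of 10, or 1 for marker lists. CPM here is gene tags per 1e6 after TMM scaling.

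Named genes followed a rule fixed before the data were examined. It took Atxn2, the 10 highest and 10 lowest ratios of each tissue, the 15 genes in each direction with the largest smallest ratio over the 3 tissues, and the highest, lowest and most abundant members of lists, leaving out clone and predicted names. Many list members and a few other genes that the rule takes are not reported here. On simulated counts for the 11375 genes, the cross-tissue fit recovered 40% of 50 genes changed 1.5-fold, 66% of those changed 2-fold and 100% of those changed 4-fold, and called 6 unchanged genes. The simulated changes were equal in all 3 tissues, and each gene had the trended spread for its level. Recovery of real genes, which vary more, may be lower. Of 2000 random lists in cerebellum, 101 fell outside the central 95%. Alternatives were other scalings, filters and size limits, DESeq2 1.42.0, limma voom, no tissue block, each tissue left out, an estimated correlation and the single highest row per symbol. Chosen after seeing the data were rows of 1 symbol only and the removal of transcripts at least 20 times higher in liver.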

Results

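Ataxin-2 is an RNA-binding protein that associates with polyribosomes and poly(A)-binding protein. Knockout and wild-type mice were compared in cerebellum, hippocampus and liver, to find transcript changes shared by the tissues. Gene tags numbered 2284820 in knockout and 2360459 in wild-type cerebellum, 2335834 and 2139501 in hippocampus, and 1774523 and 2727523 in liver. Each value within a tissue comes from 1 pool of 3 animals per genotype, so no difference within a tissue has a replicate check.

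Atxn2, on chromosome 5 from 121711609 to 121814950, was nearly absent from every knockout library. Knockout and wild-type counts were 0 and 167 in cerebellum, 1 and 194 in hippocampus, and 2 and 115 in liver. The transcript was at least 53.9-fold lower in the knockout cerebellum. The log2 ratio was -7.71 in hippocampus (95% counting interval -13.02 to -5.22). Which part of the gene was deleted is not given in the sources used here, so the 3' tags show loss of the transcript's end.

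The genotypes also differed in transcripts that mark sex, so sex may differ along with genotype in every comparison below. Xist, the X-inactivation RNA made in females, had 0 tags in each knockout library and 34, 49 and 87 tags in wild-type cerebellum, hippocampus and liver. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in both genotypes, with a summed knockout to wild-type ratio of 1.13 in cerebellum (interval 0.954 to 1.34), 1.43 in hippocampus (1.18 to 1.74) and 1.61 in liver (1.28 to 2.02). Transcripts at least 20 times higher in liver were also lower in the knockout brain libraries, with a median log2 ratio of -0.22 over 128 transcripts in cerebellum and -0.61 over 164 in hippocampus.

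Across the 3 tissues, 1 gene rose and 10 fell in the knockout at an adjusted p under 0.05 (edgeR quasi-likelihood test, 11375 genes). The alpha-globin gene Hba-a1 rose by a log2 of 0.88 (SE 0.15, adjusted p = 0.0194). The joint feature Hba-a1/Hba-a2 had more tags, with a mean of 2010 CPM in cerebellum against 182 for Hba-a1. It did not pass (log2 0.77, SE 0.23, adjusted p = 0.746), nor did Hba-a2 (log2 0.67, adjusted p = 0.195). Atxn2 fell most clearly (log2 -7.02, SE 0.39, adjusted p = 1.92e-09), beside Xist. Hamp2, a liver hormone gene of the hepcidin family on chromosome 7, fell by 5.07 on the log2 scale (SE 0.52, adjusted p = 3.03e-05), with 6 and 7 tags in knockout and wild-type cerebellum, 2 and 23 in hippocampus and 40 and 3437 in liver, which thus carries most of the evidence. The cytochromes P450 Cyp4a10 and Cyp2c54, the major urinary protein gene Mup17, the aminotransferase Ccbl2, the prolactin receptor Prlr, the mitochondrial enzyme Suclg2 and the joint feature H2-Q4/Nkain3 made up the rest of the lower genes. Several of these were scarcely present in brain, with 3 and 3 tags of Cyp4a10 and 1 and 5 tags of Mup17 in knockout and wild-type cerebellum. An unadjusted p under 0.05 was found for 555 genes. DESeq2 called 0 higher and 2 lower genes, edgeR with DESeq2 size factors 0 and 5, and edgeR without the tissue block 0 and 0. Without the block, differences between tissues enter the spread, and only 7 genes had an unadjusted p under 0.05 (edgeR). That setting thus says little on the calls. Leaving out cerebellum, hippocampus or liver gave 5 and 17, 21 and 36, or 14 and 85 higher and lower genes.

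Few abundant genes moved by a similar amount in all tissues. Among 5988 genes with at least 10 CPM in each tissue, 7 were higher and 7 lower by at least 0.5 on the log2 scale in all 3, or 14 genes, against 6, 3 and 16 after the labels were exchanged in cerebellum, hippocampus or liver. With library totals there were 18, against 5, 1 and 7. The gene with the largest smallest ratio among the higher ones was Pdcd2l, at 0.67, 0.75 and 0.63 in cerebellum, hippocampus and liver. It was followed by the joint feature Hba-a1/Hba-a2 (0.61, 0.72 and 0.98), the RNase P subunit Rpp21 (0.62, 0.60 and 0.75), and the Y-linked initiation factor gene Eif2s3y (0.58, 0.76 and 1.08). The rise of Eif2s3y cannot be told apart from a difference in sex between the pools. Hba-a1, N6amt2, Cluap1, Usp39, Hba-a2, Sh3gl1, AU019823, the autophagy gene Atg5, the thyroid hormone receptor Thra, Pddc1 and Chka/Med16 completed the 15. Among the lower genes Suclg2 came after Atxn2, at -1.11 in cerebellum and -0.89 in liver. Exosc2/Terf2ip, Erdr1, Mup15/Mup7, Nol9, the long-chain acyl-CoA dehydrogenase Acadl (-0.87, -0.77 and -0.54), Lig3, the electron-transfer flavoprotein dehydrogenase Etfdh (-0.43, -0.45 and -0.91), Mup11, Gcm1/Pigr, the myelin gene Mbp (-0.59, -0.42 and -0.76), the mRNA decay factor Patl1, Akap2 and Tspan9 followed. Suclg2, Mup15/Mup7 and Mup11 were at least 20 times higher in liver than in hippocampus. Of these 30 genes Hba-a1, Atxn2 and Suclg2 passed the edgeR test.

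Transcripts of cytosolic ribosomal proteins were higher in the knockout. The small-subunit list rose across tissues, with 33 of 34 fitted changes above 0, a median log2 of 0.23 and an adjusted p of 8.13e-20 (camera), and the large-subunit list with 48 of 49 above 0, a median of 0.17 and an adjusted p of 4.45e-17. With an estimated correlation neither list passed (adjusted p = 0.406 for each), and no single member passed when adjusted over the list alone. The series title names ribosomal subunit and initiation transcripts, so these lists are not independent evidence of direction.

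In single tissues the small-subunit median was 0.17 in cerebellum, 0.29 in hippocampus and 0.28 in liver, at percentiles 100.0, 100.0 and 96.0 of matched random lists. The large-subunit medians were 0.12, 0.17 and 0.23, at percentiles 99.99, 99.99 and 86.0. Abundant liver genes were higher in general, and the random lists matched to the large-subunit genes had medians of 0.09 to 0.27 there. In all 3 tissues 27 of 34 small-subunit and 32 of 49 large-subunit genes were higher and 0 were lower, against 13.6% higher and 13.3% lower among all measured genes. Rps19, on chromosome 7 from 24884592 to 24889811, had log2 ratios of 0.31, 0.67 and 0.33 in cerebellum, hippocampus and liver, and Rps10 of 0.20, 0.42 and 0.40. Rps27 (0.23, 0.47 and 0.34) had its tags in rows shared with near-identical copies, as did Rps27a, Rpl17, Rpl37 and Rplp2 for most of theirs, so their values are uncertain. Rps6, Rps27l and Rps27a were the lowest small-subunit members, and Rps6 was at 0.00, -0.45 and 0.49. The abundant Fau was at 0.01, 0.43 and 0.32 and Rps2 at 0.16, 0.25 and 0.34. In the large subunit, the stalk proteins Rplp1 (0.12, 0.59 and 0.28) and Rplp2 and the small protein Rpl29 were highest, and Rpl37 (-0.16, -0.11 and 0.21), Rpl5 and Rpl17 lowest. The abundant Rpl41 was at 0.08, 0.17 and 0.48.

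Translation initiation factors did not pass the cross-tissue test (median 0.06, 29 of 43 above 0, adjusted p = 0.139; 0.507 with an estimated correlation). Their medians were 0.07 in cerebellum, 0.11 in hippocampus and 0.05 in liver, at percentiles 98.2, 97.4 and 60.3. Eif3h, a subunit of the scaffold complex eIF3, was at 0.24, 0.32 and 0.34, and Eif4b at 0.27, 0.25 and 0.34, while Paip2 was at 0.04, 0.24 and 0.68. The lowest were Eif2s3x, the X-linked eIF2 gamma subunit (-0.09, -0.65 and -0.72), Paip1 and Eif3c. As Eif2s3x is X-linked, its fall cannot be told apart from a difference in sex between the pools. The abundant Eif1 was at 0.01, -0.29 and 0.56, and the poly(A)-binding protein gene Pabpc1 at -0.11, -0.13 and 0.37.

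**Figure D1:**
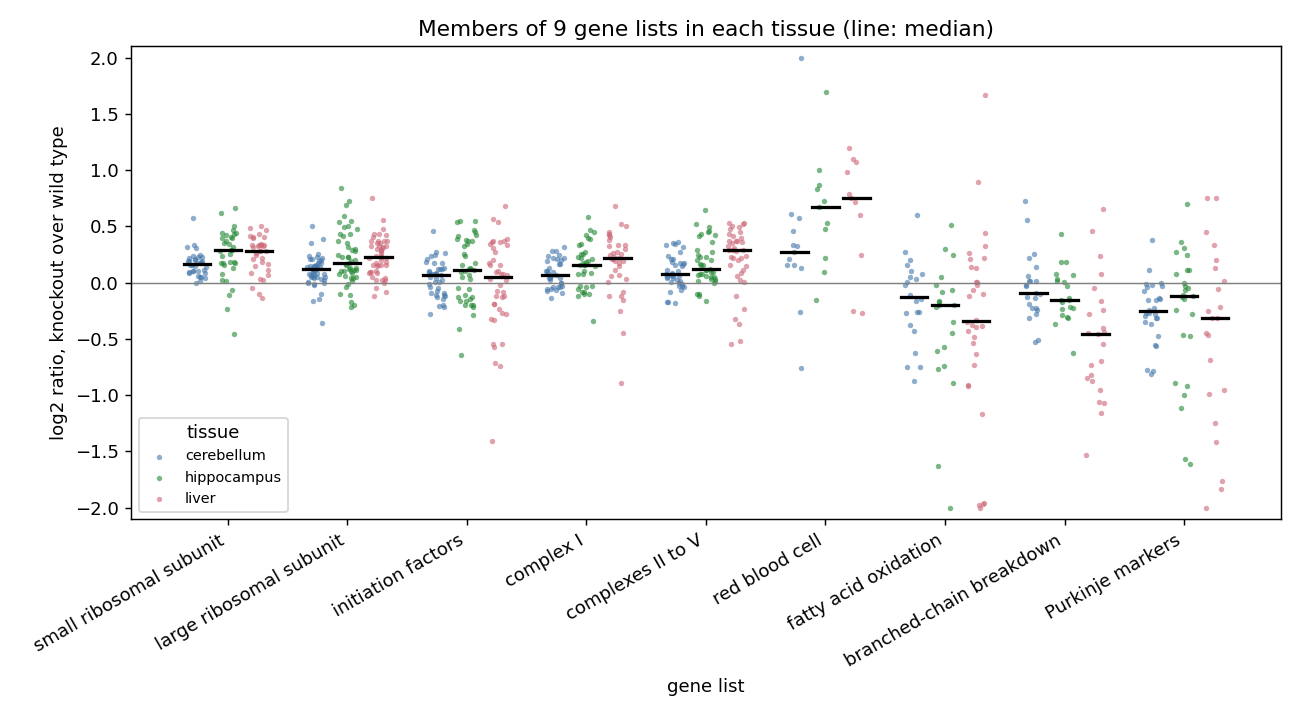
Log2 ratio of knockout over wild type (vertical axis) for the measured members of 9 gene lists (horizontal axis), with 1 point per gene, colours for tissues and black lines for medians; 4 points beyond a log2 of 2 are drawn at that limit. The small-subunit medians lie at 0.17, 0.29 and 0.28, and the fatty acid oxidation medians at -0.13, -0.20 and -0.34, in cerebellum, hippocampus and liver.

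Energy metabolism lists moved in opposite directions. Respiratory chain complexes II to V rose (median 0.18, 33 of 39 above 0, adjusted p = 1.56e-10), as did complex I (0.13, 32 of 35, adjusted p = 7.40e-07). With an estimated correlation neither passed (adjusted p = 0.406 and 0.507). Cox4i1, a cytochrome oxidase subunit, was at 0.04, 0.42 and 0.29. Fatty acid oxidation and ketone body genes fell (median -0.27, 25 of 28 below 0, adjusted p = 4.54e-09), with 10 members passing when adjusted over the list alone and 1 over all genes. The list did not pass with an estimated correlation (adjusted p = 0.406). The lowest member in hippocampus was Fabp1 (-2.14), a transcript abundant in liver. Genes of branched-chain amino acid breakdown fell (-0.23, 17 of 23, adjusted p = 1.18e-05), but not without liver (adjusted p = 0.162) or with an estimated correlation (0.507).

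Red blood cell genes rose (median 0.59, 9 of 10 above 0, adjusted p = 4.21e-14), and Purkinje cell markers fell (-0.20, 19 of 23, adjusted p = 1.80e-05). With an estimated correlation neither passed (adjusted p = 0.406 for each). The Purkinje list also passed as lower without cerebellum (adjusted p = 0.0425, camera), in tissues that hold no Purkinje cells. Its cross-tissue fall is thus not a measure of Purkinje cells alone. Transcripts at least 20 times higher in cerebellum than in hippocampus had a median of -0.85 in the hippocampal libraries, a shift that may enter the Purkinje result. Calcium and synaptic signalling genes (-0.07, adjusted p = 0.00852), insulin and mTOR signalling genes (-0.14, 0.0237) and choroid plexus markers (-0.29, 0.0237) also fell, while interferon-induced genes rose (0.15, 15 of 20 above 0, 0.0269). None of these 4 passed with an estimated correlation (0.406 for calcium and synaptic signalling, 0.507 for the others). Glycolysis and gluconeogenesis genes passed as higher (0.11, 0.0269), but with 11 of 20 above 0, a mean of 0.016, and adjusted p = 0.756 without liver, 0.0576 with rows of 1 symbol only and 0.507 with an estimated correlation. Each of these 5 lists failed to pass when 1 of the tissues was left out.

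In cerebellum 12 genes were higher and 27 lower by the size rule, or 34 and 45 with library totals. The neutrophil genes S100a9 and S100a8 were 2.41-fold and 2.26-fold higher in the knockout, and Zfp266, Abcc1, Fat2, Spag7, Prg4, Fbln1 and the joint features Bcas2/Mrpl9/Ogdh and Ankfy1/Casc4/Tmod3 were 2.02-fold to 2.43-fold higher. Below Atxn2, the lowest genes were made in liver, namely Bhmt (3.42-fold lower), Serpina1a, Serpina3k, Serpina1c, Serpina1a/Serpina1b, the fibrinogen gene Fga, Hpx and Mup20, with Fam176a the exception. Of the 27 lower genes 17 were at least 20 times higher in liver. Without such transcripts the counts were 12 higher and 10 lower. Purkinje markers had a median of -0.26 in cerebellum (percentile 0.00), with 26 of 28 lower. Pcp2, a Purkinje-specific gene, was at -0.14 (interval -0.19 to -0.10) and Doc2b at -0.82, against 0.38 for Plcb4. Choroid plexus markers had a median of -0.55 (percentile 0.00), with Ttr, the transthyretin gene, at -0.53 (38396 and 26548 CPM in knockout and wild-type liver, against 2478 and 3577 in cerebellum), and cholesterol biosynthesis genes a median of -0.31 (percentile 0.01), with 13 of 16 lower.

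In hippocampus 38 genes were higher and 90 lower. The highest was the ribosomal RNA feature Rs5-8s1 at 3.60-fold, and another, Rn28s1/Rn45s, was at 2.68-fold. Adck4, the channel gene Trpv2, Myef2, Psmg1, the transcription factor gene Mef2a, the radial glial gene Fabp7, Commd5 and Zfp36l2 were 2.39-fold to 3.43-fold higher. Apart from Atxn2 the 10 lowest were liver transcripts, with Serpina3m 14.04-fold, Serpinc1 10.2-fold and Ces1c 8.52-fold lower, followed by Saa2, the haptoglobin gene Hp, Pzp, Akr1c6, Serpina1a/Serpina1b and Bhmt. Of the 90 lower genes 62 were at least 20 times higher in liver, and 28 were left without such transcripts. Astrocyte markers had a median of -0.16 (percentile 1.04) and oligodendrocyte and myelin genes of -0.14 (percentile 1.38), with 20 of 25 lower. Mitochondrial ribosomal protein genes had a median of 0.16 (percentile 99.98).

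**Figure D2:**
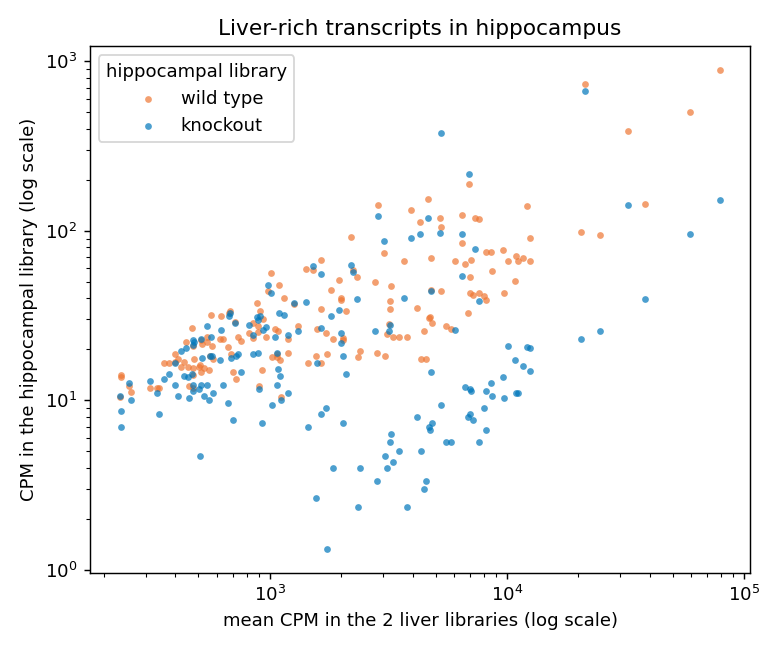
Level of 164 transcripts at least 20 times higher in liver, as CPM in each hippocampal library (vertical axis, log scale) against the mean CPM in liver (horizontal axis, log scale), with 1 point per transcript and library and colours for genotype. In wild type 143 of the 164 lie above their knockout value.

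In liver 127 genes were higher and 267 lower, or 54 and 248 with library totals and 170 and 194 with DESeq2 size factors. Cidea, which encodes a lipid droplet protein and lies on chromosome 18 from 67343564 to 67367794, had 146 tags in the knockout and 1 in wild type (log2 7.94, interval 5.44 to 13.25). Its relative Cidec had 22 and 3 tags. Sftpb, Akp3/Spen, Gpx6, the small nuclear RNA Rn7sk, the glutathione transferase Gsta1, the repressor gene Bcl6, Tff3 and Nnat were the other leading genes, with Gsta1 5.21-fold and Bcl6 4.96-fold higher. Fatty acid and triglyceride synthesis genes had a median of 0.24 (percentile 97.9), with 21 of 28 higher, and glycolysis and gluconeogenesis genes of 0.42 (percentile 100.0). Fatty acid oxidation genes had a median of -0.34 (percentile 0.00), with the thioesterase Acot2 at -2.13. Of 32 members 21 were lower, and 6 had an interval above 0. Branched-chain breakdown genes had a median of -0.46 (percentile 0.00), with Acat1 at -1.53. Of 23 members 19 were lower, and 1 had an interval above 0. Stress response and unfolded protein response genes had a median of 0.32 (percentile 99.7), with Dnajb9 at 1.41. Of 18 members 15 were higher and 3 lower, 2 of these with an interval below 0.

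Among the 10 lowest liver genes were Cyp3a41a/Cyp3a41b (272-fold lower), A1bg (at least 178-fold), Cyp2a4, Sult2a1, Cyp2c40, Cyp2c69, Sult2a5, Hamp2 (51.1-fold) and Cyp3a44. The list of female-biased liver genes, which holds many of these, had 16 of 16 members lower and a median of -4.77. Xist was at 0 and 87 tags in the same libraries. Male-biased liver genes had a median of 0.13 (percentile 48.1), with 12 of 22 higher, and the male-biased Cyp4a12a, an omega-hydroxylase, at 1.67.

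Ratios were weakly related between tissues across genes, which are not independent replicates. Pearson's r was 0.19 between cerebellum and hippocampus over 7757 genes (Spearman's rho 0.09), 0.03 between cerebellum and liver and -0.02 between hippocampus and liver. Without transcripts at least 20 times higher in liver, r between cerebellum and hippocampus was 0.08.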

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

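The tests of carry-over from liver and of cerebellar transcripts were chosen after related values were seen.

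Acute phase protein genes had a median log2 ratio of -0.65 in cerebellum and -2.20 in hippocampus but 0.40 in liver, all outside the central 95% of random lists. The liver median was 1.05 above the cerebellar and 2.60 above the hippocampal median, and the difference was not tested. Transcripts of the liver may have been carried into the wild-type brain libraries. Over liver-rich transcripts the hippocampal excess in wild type followed the liver level (Spearman's rho 0.81 across genes). A set of 27 transcripts at least 20 times higher in cerebellum was also lower in the knockout hippocampus (median log2 -0.85, random lists -0.41 to 0.30). The excess was thus not limited to liver transcripts, but this pair of tissues cannot show exchange between all libraries, so the source is open. Female-biased liver transcripts had 160 tags in wild-type and 134 in knockout hippocampus, before scaling. Carry-over at the level of the other liver-rich transcripts predicted an excess of 42.7 tags from wild-type liver and 1.2 from knockout liver. Both predictions are at wild-type depth. The knockout library was the deeper one (effective totals of 3004120 against 2782040 tags), so the unscaled difference understates the excess. The scaled excess thus lies nearer the prediction from wild-type liver. Hamp2, low in knockout liver, had 23 and 2 tags in wild-type and knockout hippocampus, but 7 and 6 in cerebellum. The excess was not tested against either prediction. An effect of genotype in brain was untested.

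Fatty acid and triglyceride synthesis genes were higher in liver and lower in hippocampus, with medians 0.46 apart, and this difference was not tested. Tags of the mitochondrial genome, which enter no comparison above, took a larger share in the knockout, by a ratio of 1.08 in cerebellum, 1.03 in hippocampus and 1.13 in liver. Antisense tags had a ratio of 1.01 in cerebellum, 0.95 in hippocampus and 0.963 in liver, so no common direction.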

How the results depend on the processing

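Genotypes were paired within tissue by the tissue block, with no replicates inside a pair. Rows of 1 symbol only and removal of liver-rich transcripts were chosen after seeing the data. Where no cause follows from the setting itself, the cause was not tested. Depth limits ratios of genes under 10 CPM.

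Cross-tissue genes higher and lower numbered 0 and 5 with DESeq2 size factors, 0 and 2 with DESeq2, 25 and 85 with no filter (22926 genes), and 0 and 0 without the tissue block. Without the block the spread holds the differences between tissues, so that count says little on genotype. Lower genes numbered 3 at 10 CPM in each tissue and 6 with voom. Leaving out a tissue gave 5 and 17 without cerebellum, 21 and 36 without hippocampus, and 14 and 85 without liver. Lists passing camera numbered 13, but 0 with an estimated correlation and 0 with fry, where both ribosomal lists had adjusted p = 0.406 and 0.271. With an estimated correlation the test has 2 residual degrees of freedom, so its 0 does not single out gene correlation as the reason.

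Counts by size, higher and lower, were 34 and 45 in cerebellum with library totals, and 54 higher in liver. With a minimum of 1 CPM they were 141 and 120 in cerebellum and 145 and 347 in hippocampus. With 50 CPM they were 0 and 0, 4 and 10, and 30 and 53 in cerebellum, hippocampus and liver. At 1.5-fold they were 114 and 174, 349 and 308, and 342 and 530. Without liver-rich transcripts 10 cerebellar and 28 hippocampal genes were lower.

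Library totals moved the liver median of all genes to -0.12 and DESeq2 size factors to 0.10. Liver medians were then 0.10 and 0.33 for the large subunit, 0.15 and 0.39 for the small subunit, and -0.058 and 0.16 for initiation factors, which stayed 0.059 above all genes. The split of liver genes was 54 higher and 248 lower with library totals and 170 and 194 with size factors. The hippocampal small-subunit median was 0.23 with rows of 1 symbol only.

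Genes of shared direction numbered 125 at a log2 of 0.25, 1 at 1 and 1 at 50 CPM. At 50 CPM r was 0.136 for cerebellum and liver and 0.014 for hippocampus and liver. Without liver-rich transcripts r was 0.076 for cerebellum and hippocampus and 0.017 for hippocampus and liver.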

Other observations

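The tests of female animals, of blood, of length by tissue and of other splits were chosen after related values were seen, and the test of length over all tissues before its result. Immediate early genes had a median log2 ratio of 0.42 in liver (percentile 99.3), but of -0.18 in cerebellum (percentile 4.61) and -0.05 in hippocampus (percentile 27.4), both inside the central 95% of random lists. Their lowest member in cerebellum was Fos, an activity-induced gene, at -1.16 (interval -1.73 to -0.61). Interferon-induced genes had medians of 0.24 in cerebellum (percentile 98.6) and 0.24 in liver (percentile 99.4), and of 0.33 in hippocampus (percentile 94.7, inside the central 95%), with Ifit3 at 0.82 in cerebellum and Usp18 at 1.10 in liver. Members higher were 6 of 8 in cerebellum, 4 of 5 in hippocampus and 14 of 22 in liver. In hippocampus and in liver 1 member had an interval below 0, and the hippocampal mean was 0.10. In hippocampus the calmodulin gene Calm3, the lowest of the calcium and synaptic signalling genes, was at -0.57 (interval -0.64 to -0.50). Genes next to Atxn2 on chromosome 5 had medians of 0.02, 0.01 and -0.07 in cerebellum, hippocampus and liver, inside the central 95% of random lists in each.

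The loss of female-biased liver transcripts may come from female animals in the wild-type pool alone. Xist had at least 34 tags in each wild-type library and 0 in each knockout library, as that explanation needs. A genotype effect on these transcripts (median log2 -4.77) cannot be told apart from one of sex, since Xist was found in wild type alone. Y-linked tags were present in both genotypes, so the wild-type libraries held transcripts of both sexes. The summed Y-linked knockout to wild-type ratio was 1.13 in cerebellum (interval 0.954 to 1.34), 1.43 in hippocampus and 1.61 in liver. Fewer males in the wild-type pool would raise it. The sex of the animals is open for every other difference between the genotypes as well, in liver, in brain and across tissues.

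The rise of ribosomal protein transcripts was set against transcript length and blood. Matched on expression and length, the ribosomal median lay at percentile 100.0 in both brain tissues, which argues against length as the cause there, but at 94.67 in liver, where length and expression may account for it. Red blood cell genes were higher in the knockout, so more blood there stays open. The ribosomal excess was above the globin excess by at least 2458 CPM in every tissue. As far as the counted globins go, this argues against blood as the source of the whole ribosomal rise. The globin excess left out features under the symbol Beta-s, such as Beta-s/Hbb-b1, so the margin may be smaller. Sex, the pooled animals and genotype stay open, untested.

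The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The genotype split called 11 genes and the highest other split 24, and 5 splits called at least as many as the genotype split, counting it. With the tissue block, a split that parts 1 tissue alone compares the genotypes within that tissue. The splits with 24 genes part hippocampus alone and those with 12 part liver alone, so they are no reference for chance. The other splits that part all tissues called 0, 0 and 2 genes.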
